A study of Drosophila melanogaster with 15 samples.

How the data were processed

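The series held 15 samples of w[1118] embryos aged 3-4 hours: 3 control samples and 3 samples each at 5, 30, 60 and 90 min after 500 µGy of gamma rays. Per the labels' protocols, eggs were laid for an hour and the embryos were kept at a constant temperature and frozen at the same age in each group, so the irradiated groups differ in how long before freezing they were irradiated. They therefore also differ in their age at irradiation, which cannot be told apart from the time since irradiation. Total RNA was reverse transcribed from an oligo(dT) primer, and biotin-labelled cRNA was hybridized to 1 array per sample. The labels call the replicates biological and letter them A, B and C.

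The authors deposited a table of array intensity values made with MAS5, per the submitters' processing notes; its version is not given in the sources used here. MAS5 summarises the probes of a probe set into a single intensity on a linear scale. The scaling is not given in the sources used here, but the mean intensity after trimming 2% at either end was 500.01 to 500.02 in each deposited column, so the deposited scaling was kept. Detection calls and scanner files were not used here. Values near the background are noisy in MAS5, and log2 differences of dim probe sets can be large by chance. The precision is limited by the number of arrays.

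The platform table paired 13646 of 18952 probe sets with 1 gene symbol, 402 with several and 4904 with none; 183 were Affymetrix controls. Symbols of 13543 probe sets were looked up through their Entrez identifiers in the RefSeq table of assembly Release 6, which changed 0 of them, and 103 kept the platform symbol. Genes were named from probe sets with 1 symbol only. No coordinates are given because the table names no genome build.

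Values were transformed as log2(intensity + 1), so fold changes are on that scale and understate changes of dim probe sets. Control probe sets were left out, and probe sets with a mean log2 value at or above the 40th percentile were kept, leaving 11261. A linear model with the 5 groups was fitted to all 15 arrays with limma 3.58.1 in R 4.3.3 (lmFit, eBayes with an intensity trend), so that all groups shared an estimate of the spread. The contrasts were each time against control, the mean of the irradiated groups against control, a linear slope per 60 min over the 4 times, and a moderated F test of any difference. Tests were two-sided with Benjamini-Hochberg adjustment and a threshold of 0.05. The median SD of a probe set was 0.764, and the median SE of a difference between 3 and 3 arrays was 0.624.

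The rule for named genes was fixed before the data were examined: up to 12 genes in each direction past the threshold at each time, with all 3 irradiated arrays on the same side of all 3 controls (up to 5 for the mean and the slope). Where fewer than 5 passed, the 5 with the smallest p in each direction were given as values that did not pass; for the F test the 10 smallest. 9 radiation-response genes were to be named whatever their values. Gene lists (21) and lists of markers of other cells or stages (5), 26 in all, were fixed at the same time. They were tested with camera in limma against all other genes (8635 genes, 1 probe set per gene, the one with the highest mean), with a preset correlation of 0.01, adjusted over 104 tests. The estimated correlation was an alternative, and fry tested each list by itself. The mean and slope contrasts of the lists, not in the plan fixed beforehand, were adjusted as a family of their own. List scores per array are means over the list's genes of log2 values centred per gene. Differences of scores were tested by exact permutation, over 455 choices of 3 control arrays or over 125 choices of 1 control per letter.

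Whether the letters pair the arrays was checked before calls were compared, by correlating the deviations of same-letter arrays from their group means. The correlations of A, B and C with control were 0.465, 0.402 and 0.665 at 5 min, 0.217, 0.375 and 0.629 at 30 min and 0.484, 0.266 and 0.607 at 60 min, all above 0.1, so the letters were taken to pair these groups. At 90 min they were 0.501, -0.299 and 0.311, so the letters did not pair that group. Counts and permutations within letters and fits with the block still include the 90 min arrays under their letter. For that group they rest on a pairing that this check did not show. The closest array in another group had the same letter for 14 of 15 arrays. The replicate letter as a fixed block, and as a random block (correlation 0.447), were alternatives fixed beforehand.

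The scripts were tested on simulated data. For 5 min against control, over 11261 probe sets and 5 runs with 100 probe sets changed by each size, the fit without a block recovered 35.8% of changes of 2 on the log2 scale and 86.8% of changes of 4 under independent noise, with a mean of 5.6 false calls. With replicate effects as in the data it recovered 24.6% and 76.8% with 0.2 false calls, and with the block 59% and 94% with 9 false calls. List tests were run on 100 simulated data sets without effects that kept the correlation between 8635 genes.

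The alternatives were a pseudocount of 32, no filter or a filter at the 60th percentile, quantile normalization, median centring, eBayes without trend or robust, array quality weights, the blocks, the arrays of a comparison alone, and leaving out each array. Added after seeing the data were the block with quantile normalization, the block with an estimated correlation for lists, the spike-in level (low or high, split at the largest gap of 0.3344) as a block, and the fit without control C, 30 min B and 90 min B. Tests of outlying samples were not run because groups held 3 arrays. Figures were drawn with matplotlib 3.10.9 under Python 3.11.15.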

Results

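Gene expression was measured in Drosophila melanogaster embryos of the w[1118] strain, a white-eyed laboratory stock, to ask how transcript levels respond to a low dose of gamma rays. Pools of embryos aged 3-4 hours had received 500 µGy of gamma rays 5, 30, 60 or 90 min before they were frozen, or no irradiation. Embryos with a longer time after irradiation were therefore younger when irradiated, and time and age at irradiation cannot be told apart. At the age of freezing the cellular blastoderm has formed, gastrulation is under way and RNA loaded by the mother is being replaced by transcripts of the embryo. Each of the 5 groups held 3 biological replicates, named A, B and C, on 1 Affymetrix array each, so that 15 arrays were compared. Each array gave an intensity per probe set, and the median over probe sets lay between 29.05 and 43.32. The number of arrays limited the precision. For the median probe set the 95% interval of a difference between 3 and 3 arrays reached 1.34 on the log2 scale to either side.

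The arrays resembled each other by replicate letter more than by treatment. Arrays of the same letter from different groups had a median correlation of 0.9483 across probe sets, against 0.8766 for arrays of the same group, where probe sets are not independent replicates. The first principal component held 42.7% of the variance and set the C arrays and the 60 and 90 min B arrays apart from the other 8 arrays, with 60 min B close to 0. The same 7 arrays that lay on its positive side had the higher level of the hybridization spike-in controls, at 11.63 or more on the log2 scale, against 11.3 or less in the other 8. The split rests on intensities alone, at a gap of 0.3344, while the levels spread over 0.3559 within the lower set and 0.3374 within the higher. This split crossed the groups: control A, control B and all A arrays were in the lower set, and control C in the higher set.

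**Figure D1:**
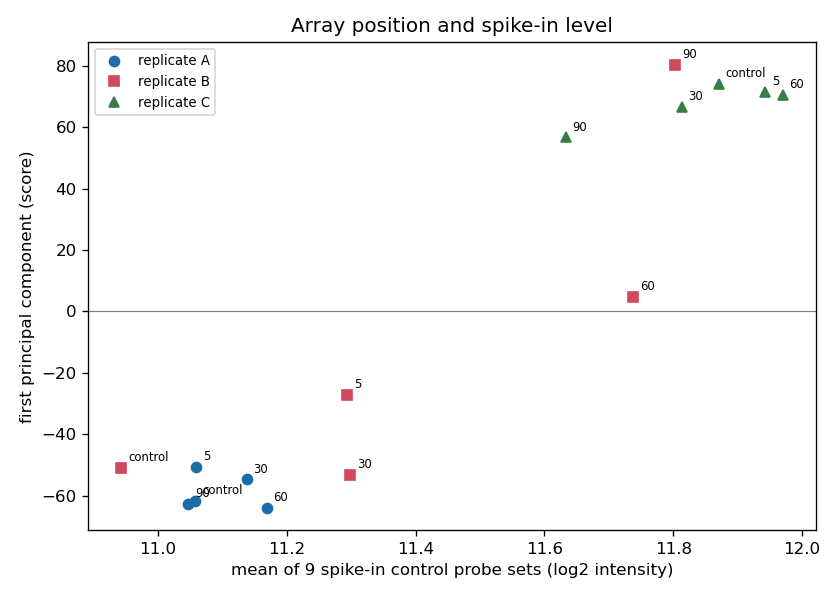
Score of each array on the first principal component (vertical axis) against the mean log2 intensity of 9 spike-in control probe sets (horizontal axis), with shapes and colours for the replicate letter and the group written beside each point (minutes after irradiation). The 7 arrays at 11.63 or above lie on the positive side and the 8 arrays at 11.3 or below on the negative side.

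Transcripts that the mother loads into the egg were lower in the irradiated arrays than in the control arrays. Of the 36 measured genes of the maternal list, 34 were lower in the mean of the 4 irradiated groups, and the list mean differed by -0.79 on the log2 scale. Among them were otu, an ovarian RNA-binding protein, at -1.70 ± 1.02 (SE), exu, which localizes bicoid mRNA, at -1.86 ± 0.78, alphaTub67C, the maternal alpha-tubulin, at -1.79 ± 0.76, and osk, the organizer of germ plasm, at -1.18 ± 0.77. Markers of the pole cells, the germline precursors, lay in the same direction: all 11 measured genes were lower, with a list mean of -0.69. They included the gap junction gene zpg at -1.36 ± 0.64 and the germline Argonaute piwi at -1.11 ± 0.61, and 3 genes of this list (osk, gcl and CycB) also belong to the maternal list. Control A had the highest score of all arrays in the maternal list (1.22) and in the pole cell list (1.20). Controls B and C scored 0.08 and 0.61 in the maternal list and 0.44 and 0.00 in the pole cell list. No member of a list passed over all probe sets. Adjusted over the list alone, 1 pole cell marker passed at 5 min, ovo (-1.52 ± 0.40), a germline transcription factor; no other list had such a member at any time, in the mean or in the slope.

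The maternal list passed camera's test with a preset correlation at all 4 times, with list means of -0.96, -0.86, -0.91 and -0.44 at 5, 30, 60 and 90 min and adjusted p between 1.09e-11 and 0.00163. With an estimated correlation its adjusted p was 0.71 at 5, 30 and 60 min and 0.765 at 90 min, so none of these calls held. Without control C the maternal list no longer passed at 90 min (-0.45, adjusted p = 0.199), nor without 90 min C (-0.24, 0.0582). With control C, 30 min B and 90 min B all left out, it was lost at 30 min (-0.52, 0.217) and 90 min (-0.45, 0.0772), and the pole cell list was lost at 30 min (-0.74, 0.135) and 90 min (-0.58, 0.118). The pole cell list passed at the same 4 times with means of -0.91, -0.55, -0.78 and -0.51, and its adjusted p with an estimated correlation lay between 0.71 and 0.765. Without control A the pole cell list no longer passed at 30 min (-0.22, adjusted p = 0.0822) and 90 min (-0.18, 0.205), and without control C it no longer passed at 90 min (-0.78, 0.0696). It was also lost at 30 min without 30 min C (-0.17, 0.32), and at 90 min without 90 min B (-0.31, 0.0713), without 90 min C (-0.26, 0.231) or with the spike-in level as a block (-0.18, 0.249). Among the 4 times fry, which asks whether a list's genes moved one way on balance, gave its smallest unadjusted p for the maternal list at 5 min (0.0564). When each letter was taken alone, the irradiated arrays differed from the control by -0.78, -0.56 and -1.04 in the maternal list for A, B and C, and by -0.54, -0.84 and -0.68 in the pole cell list. The pole cell score was below that of the same-letter control in 12 of 12 irradiated arrays, and the maternal score in 11. An exact permutation of the control array within letters (two-sided, 125 choices) gave p = 0.008 for pole cells, the smallest it can give, and 0.016 for maternal transcripts. Over 26 lists the adjusted values were 0.104 and 0.139. The exact permutation that ignores letters (455 choices of control arrays) gave p = 0.123 for pole cells and 0.0549 for maternal transcripts. Adjusted over the lists, both were 0.555. The permutation within letters treats the arrays of a letter as exchangeable. The letters did not pair the 90 min group, and 60 and 90 min B were not in the spike-in set of control B. Within the lower spike-in set the maternal list differed by -0.61 and within the higher set by -0.97, and the pole cell list by -0.51 and -0.59.

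**Figure D2:**
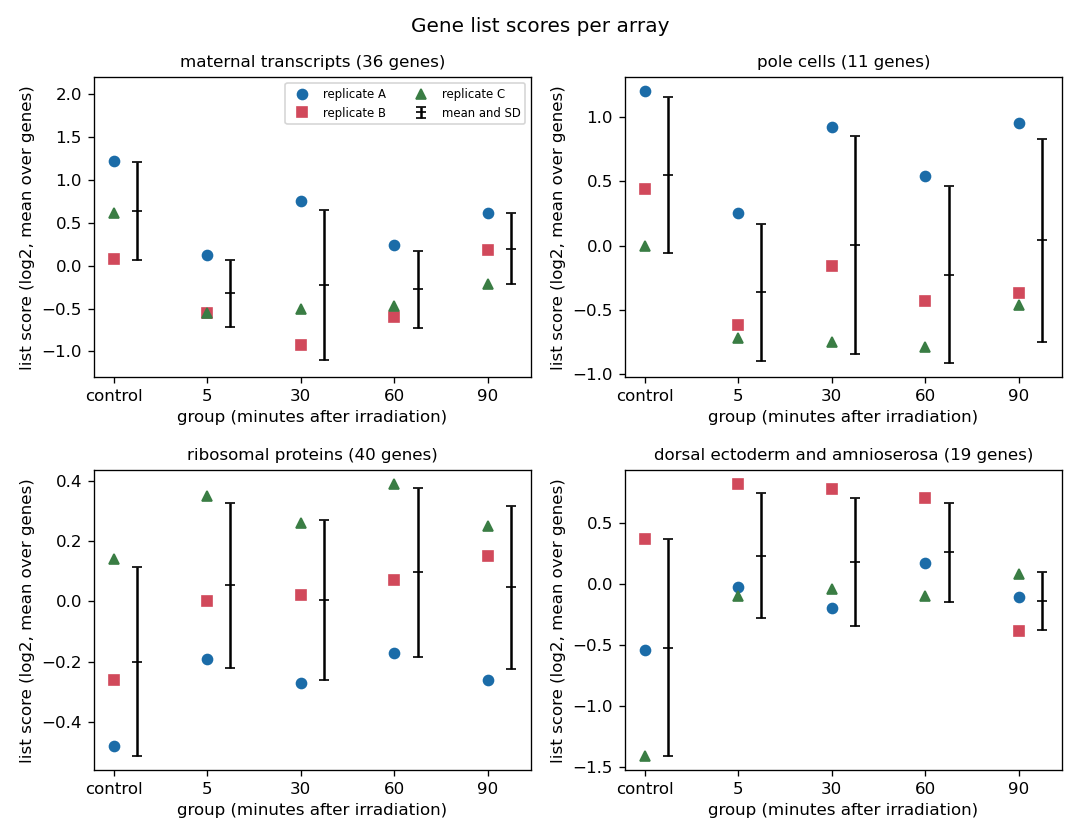
Scores of 4 gene lists (vertical axes, mean over the list's genes of log2 intensity centred per gene) on each of the 15 arrays by group (horizontal axes, minutes after irradiation), with shapes and colours for the replicate letter and bars for the mean and SD of 3 arrays. The control array had the highest pole cell score within each letter (1.20, 0.44 and 0.00), and control C had the lowest score of all arrays in the dorsal ectoderm list (-1.41).

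RnrL, the large subunit of ribonucleotide reductase, had the smallest p among probe sets that were lower in the mean of the irradiated groups. RnrL differed by -1.18 ± 0.38 (SE), and its intensity was 2223 to 4689 in the 3 control arrays and 959.3 to 3281 in the 12 irradiated ones. It was below the same-letter control in 12 of 12 arrays, as were 181 of 8635 genes (a share of 0.021). RnrL was picked by its p in this same contrast, so that count is no separate support. limma's adjusted p was 0.978 without and 0.0624 with the replicate letter as a block. The other 4 genes lower by the same rule were mtrm, an oocyte regulator of Polo kinase (-1.47 ± 0.53), BicC, a maternal RNA-binding protein (-1.45 ± 0.52), Rbf, a retinoblastoma family protein (-0.82 ± 0.27), and pds5, a cohesin cofactor (-0.73 ± 0.27), each with an adjusted p of 0.978. On the other side stood CG13744 (2.72 ± 0.47), the homeobox gene btn (3.41 ± 0.63), CG34357 (2.18 ± 0.47), Fie (2.42 ± 0.55) and the serotonin receptor gene 5-HT1B (1.66 ± 0.38). These 5 were dim, with geometric mean intensities of 21.2, 17.2, 19.3, 17.2 and 22.5, below the median intensity of every array. For CG13744 and btn the adjusted p was 0.401.

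For the mean of the irradiated groups 0 of 11261 probe sets passed limma's test at an adjusted p of 0.05, and 404 had an unadjusted p under 0.05. Chance would give 563 if the arrays were independent, but this fit leaves out the letters. Letter differences widened its spread (median SD 0.764, against 0.549 with the replicate letter as a block), which makes its p values conservative. With the replicate letter as a block the count was again 0, the smallest adjusted p was 0.0624 and 1625 had an unadjusted p under 0.05. Replicate block and quantile normalization together, chosen after the data were seen, called 19, of which 16 were higher and 3 lower.

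Genes of 4 lists of zygotic patterning genes lay on the other side. Dorsal ectoderm and amnioserosa genes were higher in 16 of 19 cases in the mean of the irradiated groups (list mean 0.66), among them the zinc finger gene peb (1.51 ± 0.73) and Ama (0.98 ± 0.45). Neuroectoderm and proneural genes were higher in 21 of 25 (0.56), among them Tom (0.94 ± 0.40), a Bearded family gene, and the Sox gene D (0.68 ± 0.24). All 10 endoderm and gut primordium genes were higher (0.65), with grn, a GATA factor, at 1.26 ± 0.53 and the hindgut gene byn at 1.02 ± 0.43. All 9 segment polarity genes were higher (0.95), with gsb at 1.92 ± 0.93 and en at 1.11 ± 0.74. By time, camera with the preset correlation called the dorsal ectoderm and neuroectoderm lists at 5, 30 and 60 min, the endoderm list at all 4 times and the segment polarity list at 30 min. Their adjusted p with an estimated correlation lay between 0.71 and 0.777. With the replicate letter as a block the segment polarity list passed at 5, 60 and 90 min as well (0.81, 0.99 and 0.82, adjusted p = 0.0433, 0.0166 and 0.0451). With the block and an estimated correlation its adjusted p was 0.786, 0.736 and 0.786. Of gap, pair-rule and Hox genes 7 of 11, 5 of 7 and 5 of 8 were higher (list means 0.14, 0.16 and 0.17).

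These patterning differences were largest within letter C. The segment polarity score of control C was -2.14 against -0.59 and 0.45 in controls A and B. Within letters the segment polarity list differed by 0.06, 0.62 and 2.16 for A, B and C, the dorsal ectoderm list by 0.49, 0.10 and 1.37, the endoderm list by 0.39, 0.17 and 1.38, and the neuroectoderm list by 0.40, 0.15 and 1.12. The dorsal ectoderm, neuroectoderm and endoderm scores were above that of the same-letter control in 11 of 12 irradiated arrays and the segment polarity score in 10. The exact permutation within letters gave p = 0.048, 0.176, 0.04 and 0.056 for these 4 lists in that order, adjusted 0.208, 0.458, 0.208 and 0.208. The permutation that ignores letters gave p = 0.0769, 0.279, 0.147 and 0.147, adjusted 0.555, 0.716, 0.555 and 0.555. Within the lower and the higher spike-in set the segment polarity list differed by 0.28 and 2.30, and the dorsal ectoderm list by 0.32 and 1.43. Without control C, 16 of 104 list tests passed in place of 35, and 5 in place of 18 were higher lists. Without 30 min B 29 passed, and without control B 48. The endoderm list at 90 min was -0.08 without control C, and the neuroectoderm list at 5 min was -0.03 without 5 min B. Without control C the dorsal ectoderm list (0.31, 0.26 and 0.34 at 5, 30 and 60 min) and the endoderm list (0.10, 0.09 and 0.31) no longer passed, nor did the segment polarity list at 30 min (0.48) or the neuroectoderm list at 5 min (0.08) and 60 min (0.22). Without control A the neuroectoderm list at 5 min (0.47) and the endoderm list at 90 min (0.50) did not pass, nor the latter without 90 min A (0.43) or with no filter (0.46, adjusted p = 0.0637). Without 30 min B the segment polarity, neuroectoderm and endoderm lists at 30 min did not pass (0.42, 0.12 and 0.19), nor the endoderm list at 5 min without 5 min B (0.24). Control C also had the lowest hemocyte score (-1.74) and the lowest score for late embryonic muscle, nerve and cuticle genes (-1.36). Hemocyte markers were called at 30 min (0.83, 8 genes) and late embryo markers at 5 min (0.57, 22 genes), with adjusted p of 0.759 and 0.765 with an estimated correlation. Within letter A both lay on the other side (-0.45 and -0.55). The hemocyte call was lost without control C (0.19) or 30 min B (0.23), and the late embryo call without control C (0.04), control B (0.55) or 5 min A (0.33), or with the replicate block and quantile normalization together (0.50, adjusted p = 0.0581).

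Of 40 ribosomal protein genes, 38 were higher in the mean of the irradiated groups, with values from -0.15 (RpL22-like) to 0.85 (RpL37-2). The list mean was 0.25, and camera called it at all 4 times (0.25, 0.21, 0.30 and 0.25). The call was lost with an estimated correlation (adjusted p = 0.765 at 5 and 60 min and 0.777 at 30 and 90 min) and with quantile normalization, where the list means were 0.03, 0.04, 0.07 and 0.07 (adjusted p = 0.926, 0.514, 0.576 and 0.388). Without control A the call was lost at all 4 times (0.12, 0.07, 0.16 and 0.11), and without control B at 30 min (0.17, adjusted p = 0.0796). It was also lost at 5 min without 5 min C (0.11), at 30 min without 30 min C (0.08) and at 90 min with the spike-in level as a block (0.10, adjusted p = 0.0881). The score was above that of the same-letter control in 12 of 12 arrays, and the exact permutation within letters gave p = 0.008, adjusted 0.104. The permutation that ignores letters gave p = 0.149, adjusted 0.555. All 9 glycolysis genes were lower (-0.51), with hexokinase A, Hex-A, at -1.05 ± 0.46; the list passed at 5, 30 and 60 min (-0.65, -0.59 and -0.64, adjusted p = 0.71 with an estimated correlation), and its slope over the times did not pass (adjusted p = 0.0689). Within letters A, B and C the glycolysis list differed by -0.84, 0.26 and -0.94 (permutation p = 0.088, adjusted 0.286) and the heat shock and chaperone list by -0.64, 0.15 and -0.36 (p = 0.336, adjusted 0.596). Without control C the glycolysis list passed at none of these times (-0.34, -0.28 and -0.33), without 5 min B not at 5 min (-0.43) and without 30 min B not at 30 min (-0.37). The heat shock and chaperone list was lower at 30 min (-0.51) and 60 min (-0.40), with Hsp27 at -1.50 ± 0.76 at 30 min; with an estimated correlation the adjusted p was 0.71 and 0.738. Without control C this list passed at neither time (-0.41 and -0.30), and at 60 min not without control A (-0.16) or 60 min A (-0.37), nor with all probe sets of a gene (-0.26, adjusted p = 0.0532). The cell cycle and replication list had means of -0.16, -0.07, -0.16 and -0.24 and was called at 90 min alone (20 of 25 genes lower, adjusted p = 0.71 with an estimated correlation); its slope over the times did not pass (adjusted p = 0.108), and without control C the call was lost (-0.37, adjusted p = 0.0588).

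In all, 35 of 104 tests of 26 lists at 4 times passed with the preset correlation and 0 passed with an estimated one. In 100 simulated data sets that kept the correlation between genes and held no effect, the preset correlation called a median of 22 of 104 and as many as 35 or more in 12 data sets. The estimated correlation made any call in 2 data sets. In these data sets letter differences fell at random over the groups, whereas each real group holds every letter. The simulations therefore cannot say how often 35 calls would arise without an effect in the real design.

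Genes of the DNA damage response gave no sign of a coordinated rise. The 9 measured genes of the p53-dependent radiation list had mean differences of -0.10, -0.01, -0.03 and -0.15 at 5, 30, 60 and 90 min, with adjusted p between 0.368 and 0.704; at 90 min the median was 0.13. In the mean of the irradiated groups 5 of these genes were lower and 4 higher. RnrL, which belongs to this list, was lowest (-1.18), followed by Irbp (-0.95). Traf4 (0.94) and skl (0.73) were highest, each above the same-letter control in 11 of 12 arrays. The pro-apoptotic gene skl differed by 0.76, 0.81, 0.79 and 0.55 (SE 0.60), and Corp, a p53 target, by -0.24, -0.05, 0.37 and 0.31 (SE 0.31). Irbp, the Ku70 subunit of the end-joining complex, differed by -1.22, -0.75, -1.04 and -0.79 (SE 0.53), and its partner Ku80 by -0.15, -0.12, -0.20 and 0.13 (SE 0.57). p53 itself differed by -0.11, -0.17, -0.03 and 0.22 (SE 0.33), and the other p53 probe set, too dim for the tests, by 2.25, 0.52, 1.51 and 0.22 (SE 0.76) when no filter was applied. The 2 probe sets of egr, the fly TNF ligand, differed by 0.52, 0.53, 0.51 and -1.10 (SE 1.39) and by 0.58, 0.31, 0.33 and -0.55 (SE 1.04). For these genes limma's adjusted p was 0.998 or 1 at each time. rpr, hid and Xrp1 were not analysed here. Genes of DNA damage checkpoints and repair were lower in 28 of 37 cases (-0.33), with Snm1, a crosslink repair nuclease, at -1.23 ± 0.67; the list was called at 5, 60 and 90 min (-0.35, -0.44 and -0.39), with adjusted p between 0.71 and 0.739 with an estimated correlation. With the replicate letter as a block it passed at 30 min too (-0.14, adjusted p = 0.0341), and with the block and an estimated correlation the adjusted p there was 0.511. The exact permutation within letters gave p = 0.032, adjusted 0.208, with 11 of 12 arrays lower. The permutation that ignores letters gave p = 0.292, adjusted 0.716. The calls with the preset correlation were lost at 5 min without control A (-0.08) or 5 min C (-0.11), at 60 min without 60 min C (-0.21) and at 90 min without control A (-0.12) or 90 min C (-0.19).

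**Figure D3:**
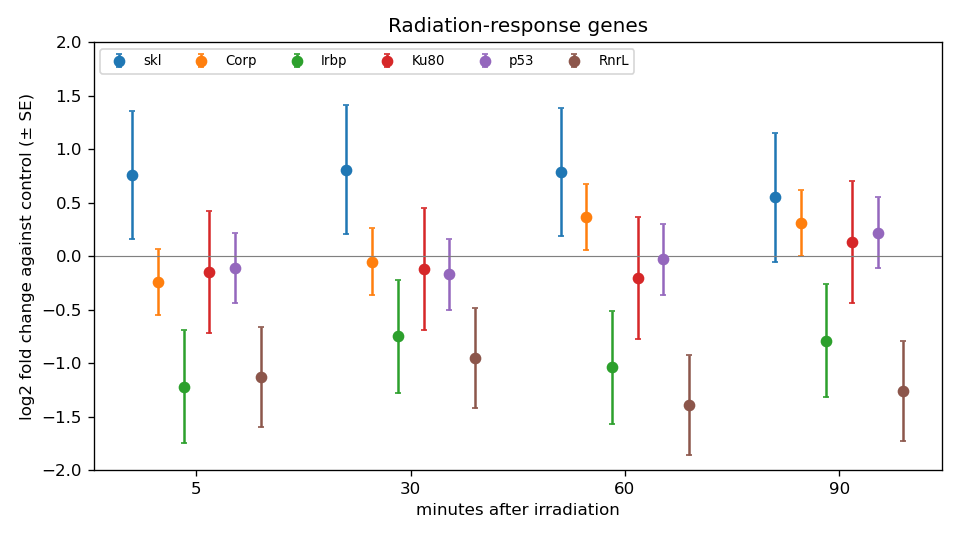
Log2 fold change against control (vertical axis, points with bars of 1 SE) at 5, 30, 60 and 90 min after irradiation (horizontal axis) for 6 genes linked to the radiation response. skl lies above 0 at each time (0.55 to 0.81) and RnrL below 0 (-1.39 to -0.95), and no value passed the adjusted threshold.

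Apoptosis, antioxidant, immune, hypoxia, proteasome, cellularization, gap, pair-rule and Hox lists, and the markers of adult females and males, were called at none of the 4 times. Some of them passed in an alternative: proteasome genes at 30 and 60 min with quantile normalization (-0.13 and -0.17), and hypoxia, gap and pair-rule genes at 60 min with the spike-in level as a block (0.58, 0.72 and 1.13). Without 30 min A the cellularization list passed at 30 min (-0.76), and without control C the pair-rule list at 90 min (-1.45). The apoptosis list differed by 0.06, 0.05, -0.05 and -0.01 (12 genes), the antioxidant list by -0.06, -0.02, 0.00 and 0.09 (30 genes) and the proteasome list by -0.01, -0.07, -0.06 and -0.06 (29 genes). Some medians had the other sign than the mean in these 3 lists, in the immune and mesoderm lists at 90 min, the hypoxia list at 60 min and the male list at 5 min, the largest being 0.29 for immune genes. The immune list differed by -0.17, -0.21, -0.16 and -0.03 (10 genes), and the hypoxia list by 0.09, 0.50, -0.01 and -0.28 (7 genes). Gap genes differed by 0.24, 0.17, 0.25 and -0.12, pair-rule genes by 0.33, 0.35, 0.45 and -0.47, Hox genes by 0.17, 0.18, 0.44 and -0.10 and cellularization genes by 0.13, -0.40, 0.10 and -0.05. The female list differed by 0.35, 0.66, -0.03 and 0.18 and the male list by 0.01, -0.11, 0.14 and 0.14. The mesoderm list was called at 30 min alone among the times (0.55, adjusted p = 0.765 with an estimated correlation), and not without control C (0.02), 30 min A (0.69) or 30 min B (0.04).

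At 5 min after irradiation the smallest p values belonged to CG13744 (2.72 ± 0.59), btn (3.48 ± 0.80), CG34357 (2.27 ± 0.59), CG32647 (2.73 ± 0.72) and cmpy (2.62 ± 0.71) on the higher side. On the lower side stood HisT (-2.57 ± 0.61), app (-2.06 ± 0.54), CG42269 (-1.39 ± 0.43), the gustatory receptor gene Gr43a (-1.83 ± 0.57) and ovo (-1.52 ± 0.40). Of these 10, ovo was bright, with a geometric mean intensity of 1165. None passed: 0 of 11261 probe sets were called, each with an adjusted p of 1, and 296 had an unadjusted p under 0.05. With the replicate letter as a block the count was 0 and 1247 had an unadjusted p under 0.05.

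At 30 min btn (3.54 ± 0.80), CG13744 (2.35 ± 0.59) and cmpy (2.50 ± 0.71) again had small p values, with CG3078 (2.52 ± 0.71) and CG13443 (1.82 ± 0.52). The lower side held mus101, a replication and checkpoint protein (-1.63 ± 0.58), Gr28a (-2.20 ± 0.69), alpha-Est9 (-1.84 ± 0.59), CG15046 (-1.99 ± 0.72) and CG43066 (-1.72 ± 0.63). limma called 0 probe sets, the smallest adjusted p was 1 and 165 had an unadjusted p under 0.05; with the block the counts were 0 and 760.

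At 60 min CG13744 (3.14 ± 0.59) and btn (4.27 ± 0.80) had the smallest adjusted p, 0.658, followed by Ids (2.44 ± 0.58), CG13443 (2.05 ± 0.52) and hgo (2.76 ± 0.77). The lower side held Rbf (-1.08 ± 0.34), pds5 (-1.08 ± 0.34), the cohesin loader gene Nipped-B (-1.84 ± 0.60), Lcp65Ad (-2.61 ± 0.65) and CG8565 (-2.51 ± 0.72). Rbf and pds5 had geometric mean intensities of 491 and 853, whereas Nipped-B, Lcp65Ad and CG8565 were dim, at 19.8, 15.6 and 17. The count of calls was 0 by limma and 278 had an unadjusted p under 0.05; with the block the counts were 0 and 1288.

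At 90 min RnrL (-1.26 ± 0.47) joined the lower side with CG34347 (-2.76 ± 0.73), CG15528 (-2.17 ± 0.64), Shrm (-2.10 ± 0.65) and Loxl1 (-2.12 ± 0.71). CG13744 (2.68 ± 0.59), CG34357 (2.61 ± 0.59), Fie (2.79 ± 0.69), CG14856 (3.48 ± 0.89) and CG14285 (3.20 ± 0.82) stood on the higher side. limma called 0 probe sets, the smallest adjusted p was 0.998 and 180 had an unadjusted p under 0.05; with the block the counts were 0 and 1074. Array quality weights, which gave weights of 8.42 to 60 min B and 8.28 to 90 min C, called 1335 probe sets at this time, 577 higher and 758 lower.

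Over the 4 times after irradiation, without the control, HisT (2.03 ± 0.40 per 60 min), Gr43a (1.38 ± 0.38), app (1.21 ± 0.36), Fem-1 (1.31 ± 0.44) and ovo (0.86 ± 0.27) had the smallest p among positive slopes. Shrm (-1.99 ± 0.43), the cuticle gene TwdlQ (-2.39 ± 0.68), lncRNA:CR40465 (-1.54 ± 0.46), CG32026 (-1.84 ± 0.55) and CG18327 (-1.72 ± 0.53) had the smallest p among negative ones. limma called 0 probe sets for the slope, with 150 at an unadjusted p under 0.05, and 0 for any difference among the 5 groups, with 94. With the block the counts were 0 and 475 for the slope and 0 and 529 for any difference, and array quality weights called 579 for any difference. In the test of any difference Lcp65Ad, CG13744, btn, HisT, Shrm, Gr43a, Ids, CG34357, CG13443 and CG8565 had the smallest p, each with an adjusted p of 1.

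The log2 fold changes of the 4 times resembled each other, as comparisons against the same 3 control arrays do. Their correlations across 11261 probe sets, which are not independent replicates, lay between 0.55 and 0.77. In 100 simulations of unchanged groups against shared controls the mean correlations lay between 0.43 and 0.52, and each observed value was inside its simulated 95% range. These ranges were wide, such as -0.24 to 0.95 for 5 and 30 min and -0.56 to 0.91 for 5 and 90 min. Letter differences fell at random over the simulated groups, which the real groups balance. The simulations therefore can neither show nor exclude a resemblance beyond the shared controls. The observed covariances differed from the simulated means by -0.08 to 0.03. No call was shared between times because there were none. The 3 control arrays could not be split into parts of at least 2, so part of the resemblance may come from the shared controls.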

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

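Except for the choices of another control per letter in the blocked fit and the lists' slopes, the tests in this part were chosen after the result was seen. The slopes of the lists were not in the plan fixed beforehand, which tested lists at the 4 times alone, but were set before any list result was seen. For 4 lists the change over time among the irradiated groups passed camera's test with a preset correlation: maternal transcripts (0.32 per 60 min on the log2 scale, adjusted p = 2.10e-04), pair-rule genes (-0.50, 0.0414), mesoderm and ventral furrow genes (-0.34, 0.04) and late embryo muscle, nerve and cuticle genes (-0.27, 0.0414). With an estimated correlation the adjusted p of each was 0.803. Within letter B, time and spike-in level went together: its 5 and 30 min arrays were in the lower set and its later arrays in the higher. Pair-rule scores at 5, 30, 60 and 90 min were 1.21, 0.98, 0.61 and -1.20 in B. They were 0.59, 0.63, 1.25 and 0.73 in A and -1.19, -0.97, -0.92 and -1.34 in C. From 5 to 90 min mesoderm scores went from 0.86 to -0.61 in B, from 0.05 to 0.12 in A and from -0.58 to -0.48 in C. With the replicate letter as a block the late embryo list was no longer past the threshold (0.0715), and the dorsal ectoderm list (-0.22) passed (0.0318 with and 0.0797 without the block, and 0.858 with the block and an estimated correlation). The late embryo score at 90 min was -0.87 in B, against 0.33 in A and 0.03 in C. The slopes of lists were not refitted without single arrays or with the spike-in level as a block, so they may rest on single arrays. A longer time after irradiation also meant a younger age at irradiation, and the slopes cannot separate time from age.

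The maternal list was lower in irradiated than in control arrays by 0.79 on the log2 scale (-0.79). Without control C and with letters as a block the difference kept its sign, at -0.669 (95% interval -1.23 to -0.11). That value rests on controls A and B alone, and the interval treats the irradiated arrays of all times as replicates. A dependence on control C is therefore not excluded. A part of the spike-in level remains open: with the level (low or high) as a block the difference was -0.736. An exact permutation of the controls within the low and high sets (196 choices, two-sided) gave p = 0.0663. Younger embryos in the control pools also stay open: with an index of all 8 patterning lists as covariate the difference was -0.57 (-0.91 to -0.23), and with an index of the 4 lists seen to be higher, a choice made from the outcome, -0.483 (-0.90 to -0.07). The index of 8 lists is not purely zygotic, since its Hox list shares bcd with the maternal list. The groups were frozen at the same age per the labels, and a response to irradiation is open as well. Whether the 4 patterning lists were higher through control C alone stays open: their index was higher by 0.70 with all arrays and by 0.298 without control C, with an interval (-0.46 to 1.06) that holds both 0 and 0.70.

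The first principal component set 7 arrays apart, all C arrays with 60 min B and 90 min B. RNA degradation, which would raise the 3' minus 5' log2 signal of control genes, stays open: that of actin was lower on these arrays by 0.281 (-0.281, exact permutation p = 1.55e-04), that of eIF-4a higher by 0.147 (p = 0.0261) and that of GAPDH by 0.026 (p = 0.79). A labelling or hybridization difference stays open too. Of these 7 arrays, 7 were those with the higher spike-in level (two-sided Fisher exact p = 1.55e-04), a match noticed before it was tested. The spike-in level and the component were both computed after every array was scaled to the same trimmed mean. The upper quartile of intensity also separated the sets: 337.1 to 421.1 on the 7 arrays, 429.8 to 595.6 on the others. The match therefore cannot tell labelling or hybridization from a difference in the embryos' RNA. Embryo age stays open: the maternal list differed between the 2 sets of arrays by -0.415 (exact permutation p = 0.198) and the index of 4 patterning lists by -0.43 (p = 0.271). Pair-rule scores, not in that index, ran from -2.09 to -0.92 on the 7 arrays except 60 min B (0.61). On the other arrays they ran from 0.47 to 1.25. Gap scores ran from -1.47 to -0.57 except 60 min B (0.29), and from 0.16 to 0.98 on the other arrays. These lists were not tested for this split. No biological explanation from the design was tested, because each set holds irradiated and control arrays.

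Other splits of the arrays were compared with the real counts, which were 0, so every split ties or exceeds them by construction. For each time, 3 against 3 arrays make 10 splits, too few for a share under 0.05; all 10 gave at least 0, and the highest other count was 0 at 5, 30 and 60 min and 2 at 90 min. For the mean of the irradiated groups, any difference and the slope, 100 of 100 splits gave at least 0, which a count of 0 fixes in advance and which decides nothing about chance. The highest other counts were 2241, 2646 and 4162. Splits that call that many probe sets point to a structure of the arrays other than the treatment. In the blocked fit of the mean of the irradiated groups, 1625 probe sets had an unadjusted p under 0.05. Of 100 choices of a control array per letter, 6 gave as many, the real one included, and the highest other gave 2952, so chance cannot be excluded there.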

How the results depend on the processing

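Apart from alternatives named as added after seeing the data, all were fixed beforehand. The count of 0 probe sets held in 197 combinations of comparison and alternative, including every fit without 1 array, and moved in 3. Array quality weights gave 1335 calls at 90 min and 579 for any difference, with weights of 8.42 and 8.28 on 2 arrays estimated from groups of 3. Replicate block with quantile normalization, added later, gave 19 for the mean of the irradiated groups; the cause was not tested. The replicate block alone gave 0 calls in each comparison and 39 list calls in place of 35, 35 of them shared. The 4 added were segment polarity at 5, 60 and 90 min and DNA repair at 30 min, and it changed no other call at these times. Among the slopes of lists it lost late embryo and gained dorsal ectoderm. As a random effect it also gave 0 calls in each comparison.

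List calls fell from 35 to 0 with an estimated correlation (smallest adjusted p = 0.71) and to 0 with the replicate block and an estimated correlation (0.111), because genes of a list vary together between arrays. Leaving out control C, 30 min B and 90 min B, which was added later, left 13. Leaving out each array in turn gave 16 to 48 list calls, with 16 without control C, 32 without control A and 48 without control B. Without control C, 30 min B and 90 min B several lists turned sign at 30 min: segment polarity -0.27, mesoderm -0.49, dorsal ectoderm -0.06, neuroectoderm -0.32, endoderm -0.35, hemocytes -0.41 and late embryo -0.75, the last of which passed (adjusted p = 0.00743); endoderm at 90 min was -0.05. With the spike-in level as a block, also added later, hypoxia genes at 60 min were at 0.58 and passed (adjusted p = 0.0317). Leaving out 1 array each, endoderm at 90 min ran from -0.08, without control C, to 0.97, and neuroectoderm at 5 min from -0.03, without 5 min B, to 1.03. The cause was not tested in these cases.

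Values that passed in neither setting were compared by call alone, and 80 of 2610 values of named genes changed sign. With median centring the median change of all probe sets was 0.151, 0.03, 0.131 and 0.141 at 5, 30, 60 and 90 min, against 0.07, 0.065, 0.058 and 0.052 in the deposited scaling. Of the 40 genes named by smallest p, 33 had a geometric mean intensity under 100, where signal over background limits what can be measured.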

Other observations

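The tests in this part were chosen after the data were seen. With the replicate block and quantile normalization together, 16 probe sets were called higher in the mean of the irradiated groups and 3 lower. The genes named here were chosen after their values were seen. Those higher included gbb (1.29 ± 0.19), a BMP ligand, Cyp310a1 (1.44 ± 0.21), a cytochrome P450, PH4alphaEFB (1.60 ± 0.26), a prolyl hydroxylase that modifies collagen, NimC4 (1.58 ± 0.27), an engulfment receptor, and Atx-1 (1.40 ± 0.18). Those called lower were RnrL (-1.15 ± 0.19), Fs(2)Ket (-1.89 ± 0.28), the fly importin beta, and osk (-1.29 ± 0.21). limma's adjusted p of the 19 calls ran from 0.0291 for Atx-1 to 0.0493 for SF2, a splicing factor (1.08 ± 0.19). With the block alone or quantile normalization alone 0 probe sets passed.

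If the arrays of a letter are exchangeable, chance puts the same-letter control below all irradiated arrays in every letter for a share of 0.008 of genes. The share for above is the same. Of all 8635 genes, the share was 0.0412 for higher in 12 of 12 and 0.021 for lower. No permutation of these shares was run. Every gene is compared with the same 3 control arrays and genes vary together, so the distance from 0.008 decides nothing about chance. Within letters, 10 of 40 ribosomal protein genes were higher than the same-letter control in 12 of 12 irradiated arrays, against 0 lower in 12 of 12; their list mean fell with quantile normalization, and genes of a list vary together. Endoderm genes were higher in 12 of 12 in 3 of 10 cases, neuroectoderm genes in 4 of 25 and dorsal ectoderm genes in 3 of 19. Among pole cell markers 4 of 11 were lower in 12 of 12 (osk, zpg, piwi and spir), and among maternal transcripts 2 of 36 (osk and otu). Among repair genes Hus1-like, a checkpoint clamp subunit, was higher in 12 of 12 (0.38), and Snm1 (-1.23) and PolZ1 (-0.70) lower in 12 of 12.

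Genes of DNA damage checkpoints and repair were lower in irradiated arrays by 0.33 (-0.33, letters as a block). Many of their transcripts are loaded maternally, and a hypothesis is that they are lower as part of the maternal pool. With the maternal score as covariate the difference was -0.477 (95% interval -0.96 to 0.00), which neither excludes nor bears out this explanation. Over the 12 irradiated arrays centred within letters, the repair score and the maternal score had r = -0.29 (permutation p = 0.625) and rho = 0.03 (p = 0.929), and r = -0.07 without the 2 farthest arrays. It was 1 of 2 relations computed, with an adjusted p of 0.625; the other, between the maternal score and the index of 4 patterning lists, had r = -0.68 (p = 0.126, adjusted 0.252), rho = -0.31 (p = 0.445) and r = -0.19 without the 2 farthest arrays.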
